A study of Homo sapiens with 6 samples.

How the data were processed

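Poly-A RNA was sequenced from 6 samples of DU145, an established human prostate cancer cell line. Of these, 3 libraries came from cells given the solvent DMSO and 3 from cells given 1 µM CCS1477 (inobrodib), an inhibitor of the bromodomain of the acetyltransferases p300 and CBP, for 24 h. Groups and replicate numbers were taken from the sample titles. The labels do not state whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

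The authors deposited 1 table of estimated counts per gene and 1 table of TPM, each with 60623 Ensembl gene IDs and 1 column per library. The deposited estimated counts were not normalized, and between 10.2% and 10.7% of the nonzero values of a library were not whole. The deposited TPM values had the same sum in each library to within rounding. Trimmomatic 0.39 is named in the submitters' processing notes. The aligner, the quantifier, the genome build and the strandedness of the counting are not given in the sources used here. Of the gene IDs, 58516 were also in GENCODE 29, and 46868 of these (80.1%) had the same chromosome and end and a start within 1 base of that GRCh38 annotation. Coordinates are printed as the files give them. Because strandedness is unknown, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies such as the histone genes may be split between them.

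Estimated counts were rounded to whole numbers. Library totals ran from 8286883 to 11956748 counts, so that 3 counts, taken as the detection floor, corresponded to 0.251 to 0.362 CPM. Such floors cover counting error only. Genes were kept by the filterByExpr rule of edgeR 4.0.16 with a minimum count of 10 and a minimum total of 15, which left 14928 of the 25155 genes with a count in any library. Normalization used TMM factors, and CCS1477 was compared with DMSO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05, without covariates. Standard errors of log2 fold changes were derived from the test statistic, and values per group are CPM as mean ± SD over 3 libraries. All computations ran in R 4.3.3, and plots were drawn with matplotlib 3.10.9.

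The comparison, its test, 39 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, a fixed set of 5 genes (of which CD274, EP300, CREBBP and MYC are given), and from each list up to 4 members with the smallest adjusted p plus up to 2 past the threshold with the opposite sign. The files hold no gene type, so genes with a symbol that is not a clone name stood in for protein-coding genes. Some genes, and 1 list, are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Lists with at least 5 tested genes (34 of the 39) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives.

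The alternatives included other scaling factors, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), other filters, a stricter threshold, a test against a fold of 1.2, the replicate number as a block and leaving out each library. Removal of GC content and length trends and a restriction to GENCODE 29 protein-coding genes were added after seeing the data.

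The procedure was tested on simulated data for this comparison, with 14928 genes of which 200 were changed, in 5 simulations per setting. With gene-wise dispersions taken from the data, edgeR recovered 39.2% of the genes changed by 1.5-fold and 71.4% of those changed by 2-fold, and 9.5% of its calls were false, above the nominal 5%. With trended dispersions it recovered 45.8% and 78.2%, with 3.52% false calls. Camera at the preset correlation found the simulated set in 10 of 10 simulations and called 0 of 400 unchanged sets, but those simulated genes were independent of each other, unlike real genes.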

Results

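RNA-seq of DU145 prostate cancer cells was used to ask how 24 h with 1 µM CCS1477, which blocks the bromodomain of p300 and CBP, changed the transcriptome relative to DMSO. There were 3 libraries per group. DMSO libraries 1, 2 and 3 held 11956748, 11931870 and 8286883 counts, and CCS1477 libraries 1, 2 and 3 held 8767277, 9412893 and 8691393. The first principal component, with 48.5% of the variance, separated the groups, and the second, with 19.9%, lay mainly between DMSO 2 and DMSO 3. Mitochondrial transcripts took 5.52% ± 0.641 of the counts in DMSO and 5.05% ± 0.720 in CCS1477 (SD, n = 3, two-sided exact permutation p = 0.5, where 0.1 is the smallest this design allows). Genes with a count numbered 20670 ± 170 in DMSO and 20070 ± 210 in CCS1477, and the normalization factors were 0.983 ± 0.00153 and 1.017 ± 0.00721 (SD, n = 3, exact permutation p = 0.1 for each).

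More genes were lower than higher after CCS1477. CEMIP, a protein involved in hyaluronan breakdown, fell from 73.0 ± 10.2 CPM to 2.24 ± 0.142 CPM, and the complement component C3 fell from 22.02 ± 2.38 to 3.16 ± 0.334 CPM (SD, n = 3), although C3 had smaller log2 differences on the log2(TPM + 1) and log2(TPM + 0.1) scales and did not pass there. The cytokine gene IL11 rose from 38.6 ± 8.36 to 134.5 ± 9.04 CPM, and CCN2, which encodes a matricellular growth factor, rose from 19.6 ± 3.14 to 67.0 ± 11.5 CPM. By edgeR's quasi-likelihood test, 1079 of 14928 genes (7.23%) were higher and 1597 (10.7%) were lower with CCS1477. Of these, 166 were higher and 459 lower by over 2-fold. Scaling by library size alone gave 1456 higher and 1361 lower, so the share of calls that were lower was 48.3% against 59.7% in the TMM fit. The counts fell to 555 higher and 973 lower without DMSO 1, to 489 and 925 without CCS1477 2, and to 487 and 1042 without CCS1477 3, and genes higher by over 2-fold fell to 101 without CCS1477 3. In all, 35.9% of tested genes had groups that did not overlap, where chance gives 10%.

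**Figure D1:**
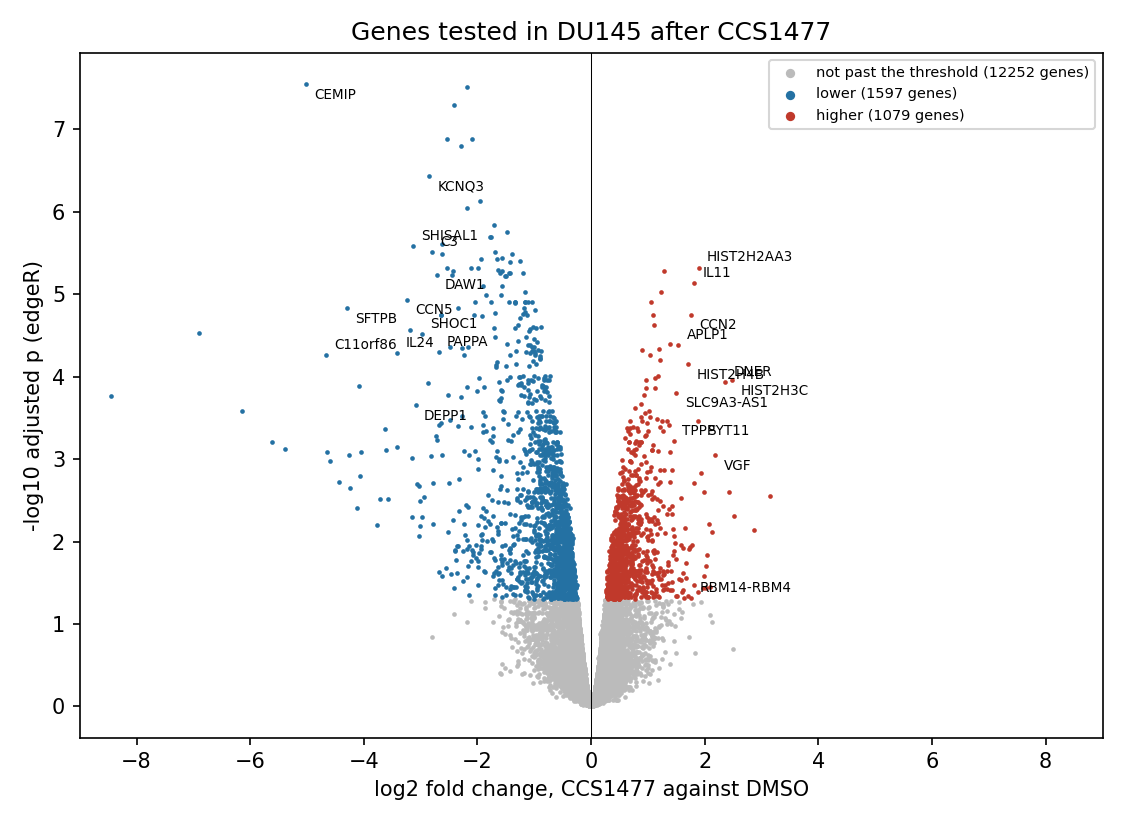
Each point is 1 of the 14928 tested genes, with its log2 fold change (CCS1477 against DMSO) on the x axis and the -log10 adjusted p of edgeR's quasi-likelihood test on the y axis. Blue marks the 1597 lower and red the 1079 higher genes, and symbols mark the 12 largest falls and 12 largest rises under the naming rule.

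The largest falls under the naming rule were led by CEMIP (chromosome 15, 80779343 to 80951776), with a log2 fold change of -5.02 ± 0.17 (SE, adjusted p = 2.8e-08, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). C11orf86 followed at -4.67, then SFTPB, a lung surfactant protein, at -4.30, the cytokine IL24 at -3.41 and CCN5 at -3.24. SHISAL1, DEPP1, SHOC1 and the potassium channel subunit KCNQ3 lay between -3.13 and -2.85. C3 fell by 2.80 on the log2 scale, DAW1 by 2.72 and the metalloproteinase PAPPA by 2.68. PAPPA stood at -0.90 on the log2(TPM + 1) scale, and SFTPB, SHISAL1, DEPP1 and SHOC1 at -2.58, -1.92, -2.01 and -1.69.

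The largest rises included histone genes. HIST2H3C rose with a log2 fold change of 2.49 ± 0.27 (SE, adjusted p = 0.000111, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), HIST2H2AA3 at 1.89 and HIST2H4B at 1.71. These have near-identical copies, so the share of each copy is uncertain. DNER, a Notch ligand of neurons, rose at 2.36, the secreted neuropeptide precursor VGF at 2.18 and the synaptotagmin SYT11 at 1.89. IL11 had a log2 fold change of 1.81, CCN2 of 1.76, APLP1 of 1.54 and TPPP of 1.45. On the log2(TPM + 1) scale SYT11 stood at 1.05 and TPPP at 0.94. RBM14-RBM4, a readthrough of RBM14 and RBM4 whose reads overlap both, stood at 1.76, and SLC9A3-AS1, which overlaps SLC9A3 on the other strand, at 1.501. RBM14-RBM4 had 9.58 CPM in DMSO 3 against 1.36 and 1.45 in the other DMSO libraries and a log2 fold change of 3.19 without DMSO 3, and its call ended in DESeq2, on both TPM scales and without any 1 of the other 5 libraries.

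CD274, EP300, CREBBP and MYC, all fixed in advance, did not pass the threshold. CD274, which encodes the checkpoint ligand PD-L1, was at 10.9 ± 1.30 CPM in DMSO and 9.11 ± 2.02 CPM in CCS1477, a log2 fold change of -0.27 ± 0.20 (SE, adjusted p = 0.403, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). EP300 and CREBBP, the genes of p300 and CBP, had log2 fold changes of 0.17 ± 0.12 and 0.01 ± 0.13 (adjusted p = 0.365 and 0.973 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). MYC stood at -0.17 ± 0.10 (adjusted p = 0.276, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

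**Figure D2:**
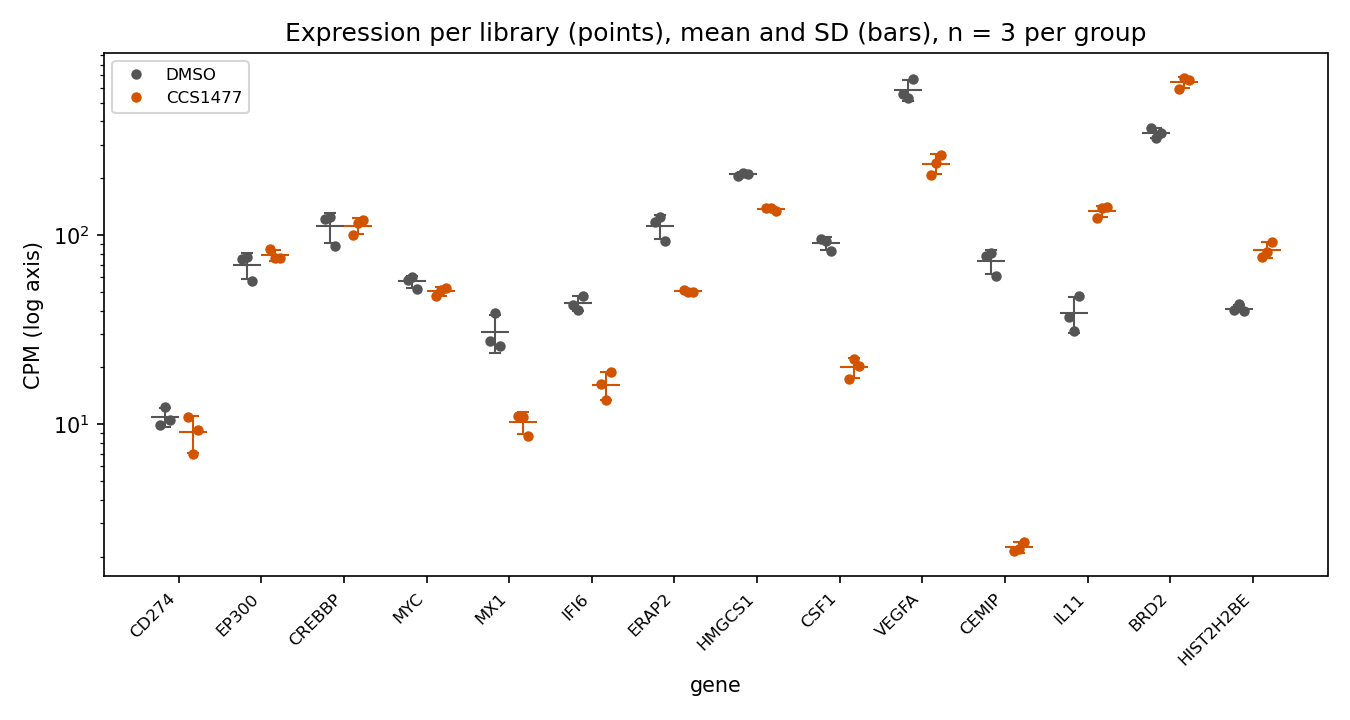
CPM on a log axis for 14 named genes in the DMSO (grey) and CCS1477 (orange) libraries, where each point is 1 library and bars show the mean and SD of 3. CD274, EP300, CREBBP and MYC overlap between the groups, while CEMIP lies at 73.0 CPM in DMSO and 2.24 CPM in CCS1477.

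Interferon-stimulated genes fell together. Of 24 tested members, 19 were lower and 0 higher, 5 did not pass, and 21 were lower when adjusted over the list alone, with a median log2 fold change of -1.03. MX1, an antiviral GTPase, fell from 30.9 ± 7.09 to 10.2 ± 1.35 CPM, IFI6 from 43.6 ± 3.95 to 16.2 ± 2.71 CPM and IFIT1, which binds viral RNA, from 38.5 ± 2.52 to 16.1 ± 2.34 CPM. Camera gave an adjusted p = 3.7e-13 for the list, and an adjusted p = 0.0583 with an estimated correlation, and limma on log2(TPM + 1) called 9 of the 24 lower. Among interferon receptors and JAK-STAT genes, 5 of 22 were lower and 0 higher (6 lower when adjusted over the list alone), among them IRF9, part of the transcription factor that drives these genes, at -1.14, and STAT3 at -0.33. That list did not pass camera (adjusted p = 0.240), and its count of lower genes was 1 without CCS1477 2, 2 without DMSO 1 and 3 without CCS1477 1 or CCS1477 3.

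Genes of MHC class I antigen presentation were lower in 9 of 21 cases and higher in 0, and in 13 when adjusted over the list alone. The peptide-trimming enzymes ERAP2 and ERAP1 fell by 1.15 and 0.80 on the log2 scale, the peptide transporter subunit TAP2 by 0.69, and NLRC5, a transactivator of class I genes, by 0.97. The heavy-chain genes HLA-B and HLA-C and the light chain B2M, chosen after their values were seen, had log2 fold changes of -0.31, -0.28 and -0.06, and did not pass. Limma on log2(TPM + 1) or log2(TPM + 0.1) called 0 of the 21 lower. The camera adjusted p = 4.8e-06 became an adjusted p = 0.235 with an estimated correlation. In the MHC class II list, 1 of 8 genes was higher (HLA-DQB1) and 1 lower (CD74), and 2 and 2 when adjusted over the list alone (camera adjusted p = 0.905). The call of HLA-DQB1 ended in DESeq2 and without any 1 library but DMSO 1, that of CD74 without DMSO 1, CCS1477 1 or CCS1477 3, and both on the 2 TPM scales.

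Checkpoint ligands and related surface proteins were lower in 7 and higher in 1 of 21 genes (8 and 1 when adjusted over the list alone). CD24, an anti-phagocytic surface protein, fell from 225.8 ± 24.5 to 75.8 ± 6.53 CPM, NT5E, which makes adenosine, from 371.7 ± 37.8 to 146.3 ± 17.8 CPM, and VSIR, the gene of the checkpoint protein VISTA, fell by 0.90 on the log2 scale. ULBP2, a ligand of the activating receptor NKG2D, rose at 1.16. The count of lower genes was 3 without DMSO 1 or CCS1477 1 and 4 without CCS1477 2. The camera adjusted p = 0.00994 became an adjusted p = 0.216 with an estimated correlation.

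Chemokines and cytokines were lower in 8 and higher in 2 of 18 genes (9 and 3 when adjusted over the list alone). The macrophage growth factor CSF1 fell from 90.6 ± 6.85 to 20.04 ± 2.47 CPM, and the neutrophil chemokines CXCL2 and CXCL8 fell by 1.68 and 1.07 on the log2 scale, while IL11 and TGFB1 rose. Camera gave an adjusted p = 0.00367, and an adjusted p = 0.193 with an estimated correlation. NF-κB targets were lower in 7 and higher in 1 of 21 genes (8 and 2 when adjusted over the list alone), with the caspase-8 regulator CFLAR at -1.04, TNFAIP3 at -1.12 and NFKB2 at 0.47. Their camera adjusted p = 0.0077 became an adjusted p = 0.216 with an estimated correlation.

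Cholesterol and fatty acid synthesis genes were lower in 18 of 29 cases and higher in 0, and in 26 when adjusted over the list alone. HMGCS1, an early enzyme of the mevalonate pathway, fell from 211.0 ± 4.08 to 138.2 ± 2.75 CPM, the desaturase SCD fell by 0.55, INSIG1 by 0.66 and the sterol enzyme MSMO1 by 0.52 on the log2 scale. Without DMSO 1, CCS1477 1 or CCS1477 2 the lower genes numbered 9, 11 and 9, and limma on log2(TPM + 1) or log2(TPM + 0.1) called 1 lower. Camera gave an adjusted p = 1.4e-10, and an adjusted p = 0.141 with an estimated correlation.

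In the epithelial-mesenchymal transition list, 14 of 25 genes were lower and 1 higher (15 and 2 when adjusted over the list alone). Both epithelial and mesenchymal members fell: the adhesion gene CDH1 fell by 1.17 and the matrix gene TNC by 2.42 on the log2 scale, with the protease PLAU at -0.73, while the epithelial splicing factor ESRP2 rose at 0.45. Lower genes numbered 8 without DMSO 1, CCS1477 1 or CCS1477 2. Camera gave an adjusted p = 1.3e-06, and an adjusted p = 0.127 with an estimated correlation. TGF-β genes were lower in 9 and higher in 0 of 20 cases (9 when adjusted over the list alone), including LTBP2 at -1.28, the receptor TGFBR2 at -0.84 and the signal transducer SMAD3 at -0.69 (camera adjusted p = 0.00135, and adjusted p = 0.235 with an estimated correlation). YAP/TAZ-TEAD targets were lower in 9 and higher in 2 of 22 (13 and 3 when adjusted over the list alone). TGFB2 fell by 2.35 (-1.36 on the log2(TPM + 1) scale), while the classical targets CCN2 and CCN1 rose at 1.76 and 0.41 (camera adjusted p = 0.00453, and adjusted p = 0.375 with an estimated correlation).

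Receptor tyrosine kinases and growth factors were lower in 11 and higher in 2 of 23 genes (13 and 2 when adjusted over the list alone). The EGFR ligands EREG and AREG fell by 1.95 and 1.00 and IGFBP3, which binds insulin-like growth factors, by 2.65 on the log2 scale, while the receptor EPHA2 rose at 0.65 (camera adjusted p = 0.00288, and adjusted p = 0.235 with an estimated correlation). Lower genes of this list numbered 7 without DMSO 1, CCS1477 1 or CCS1477 2. Hypoxia genes were lower in 9 and higher in 1 of 28 (11 and 3 when adjusted over the list alone). VEGFA fell from 586.4 ± 76.1 to 239.2 ± 29.3 CPM and NDRG1 from 240.6 ± 22.8 to 80.3 ± 13.7 CPM, while the glycolytic enzyme ALDOA rose at 0.35. Lower hypoxia genes numbered 4 without DMSO 1. The camera adjusted p = 0.0103 became 0.0854 without CCS1477 1, and an adjusted p = 0.478 with an estimated correlation.

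MYC targets were lower in 7 and higher in 1 of 26 genes (10 and 1 when adjusted over the list alone), with the lactate dehydrogenase subunit LDHA at -0.54, the folate carrier SLC19A1 at -0.53 and the polyamine enzyme ODC1 at 0.54 (camera adjusted p = 0.00885, and adjusted p = 0.235 with an estimated correlation). Lower MYC targets numbered 4 without DMSO 1, 3 without CCS1477 1 and 2 without CCS1477 2 or CCS1477 3. Unfolded protein response and ATF4 targets were lower in 7 and higher in 0 of 22 (7 lower and 1 higher when adjusted over the list alone), including the amino acid transporter SLC7A5 at -0.82 and the chaperone HSP90B1 at -0.62 (camera adjusted p = 0.00453, and adjusted p = 0.375 with an estimated correlation), with 3 lower without DMSO 1 and 4 without CCS1477 1 or CCS1477 2. Cytosolic ribosomal protein genes were lower in 2 and higher in 0 of 47 (0 when adjusted over the list alone), namely RPL30 and RPS23, against 5 lower in DESeq2, 6 with GC and length trends removed (and 1 higher), 8 without a filter and 0 with scaling by library size. Their camera adjusted p = 0.00453 became 0.196 without DMSO 3 and 0.0854 without CCS1477 1, and an adjusted p = 0.610 with an estimated correlation. RPS27 stood at 1310 CPM in DMSO 3 against 677.3 and 551.7 CPM in the other DMSO libraries.

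Replication-dependent histone genes rose: of 12 tested, 8 were higher, 0 lower and 4 did not pass (9 higher when adjusted over the list alone), with a median log2 fold change of 0.69. The list was written in advance as a check of RNA quality and poly-A selection. Poly-A RNA was sequenced, so these counts need not follow total histone mRNA. HIST2H2BE rose from 41.0 ± 1.89 to 83.9 ± 7.94 CPM and HIST1H2BD at 0.80. Counts summed over the 59 histone genes with a count, which does not depend on how reads are split between copies, rose from 675.2 ± 28.8 to 1259 ± 99.2 CPM, a log2 fold change of 0.90 ± 0.09 (SE, adjusted p = 3.5e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The rise was uneven: the 16 such genes on chromosome 1 went together from 347.5 ± 2.26 to 847.6 ± 73.1 CPM, a log2 fold change of 1.29 ± 0.09, and the 42 on chromosome 6 from 327.1 ± 28.9 to 410.4 ± 27 CPM, 0.33 ± 0.09 (SE, adjusted p = 3.1e-06 and 0.0303 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The chromosome 6 sum did not pass without DMSO 1, CCS1477 2 or CCS1477 3. These sums were chosen after the data were seen. Without CCS1477 3, 4 of the listed genes were higher. Camera gave an adjusted p = 2.4e-06 for the list, and an adjusted p = 0.234 with an estimated correlation. The S phase list had 4 genes higher and 2 lower of 31 (the same counts when adjusted over the list alone, camera adjusted p = 0.240), with 2 higher without DMSO 1, CCS1477 2 or CCS1477 3. The G2 and M phase list had 0 higher and 4 lower of 31 (the same when adjusted over the list alone, camera adjusted p = 0.499), with 1 lower without DMSO 1 or any 1 CCS1477 library.

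The acetyltransferase and bromodomain list, which also held HEXIM1, had 4 higher and 0 lower of 20 (4 when adjusted over the list alone). The 4 were BRD2, HEXIM1, TRIM28 and SMARCA2, and no acetyltransferase gene was among them. BRD2, a BET bromodomain protein, rose from 348.1 ± 21 to 645.1 ± 43.7 CPM, and HEXIM1, an inhibitor of the elongation factor P-TEFb, rose at 0.71 and TRIM28 at 0.48. SMARCA2 rose at 0.30 in this test, but had log2 differences of -0.13 and -0.13 on the log2(TPM + 1) and log2(TPM + 0.1) scales, and did not pass in DESeq2, in limma-voom or without a filter. Higher genes numbered 2 without CCS1477 3. The camera adjusted p = 0.0103 became 0.0685 without DMSO 3, and an adjusted p = 0.339 with an estimated correlation. Immediate early genes were higher in 7 and lower in 2 of 24 (7 and 2 when adjusted over the list alone), including EGR1 at 0.97 and ZFP36, a regulator of mRNA decay, at 0.69, against FOSL2 at -0.66. The higher genes numbered 4 without DMSO 1 and 3 without CCS1477 2 or CCS1477 3. Their camera adjusted p = 0.0288 became 0.0685 without DMSO 3 and 0.0580 without CCS1477 3, and an adjusted p = 0.296 with an estimated correlation. NRF2 targets were higher in 4 and lower in 1 of 18 (4 and 1 when adjusted over the list alone), with the glutathione synthesis subunit GCLM at 0.63, TXNRD1 at 0.60 and the haem oxygenase HMOX1 at -0.86. The higher NRF2 targets numbered 2 without DMSO 2, CCS1477 2 or CCS1477 3. Their camera adjusted p = 0.0343 became 0.116 without DMSO 3, 0.077 without CCS1477 2 and 0.130 without CCS1477 3, and an adjusted p = 0.373 with an estimated correlation.

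**Figure D3:**
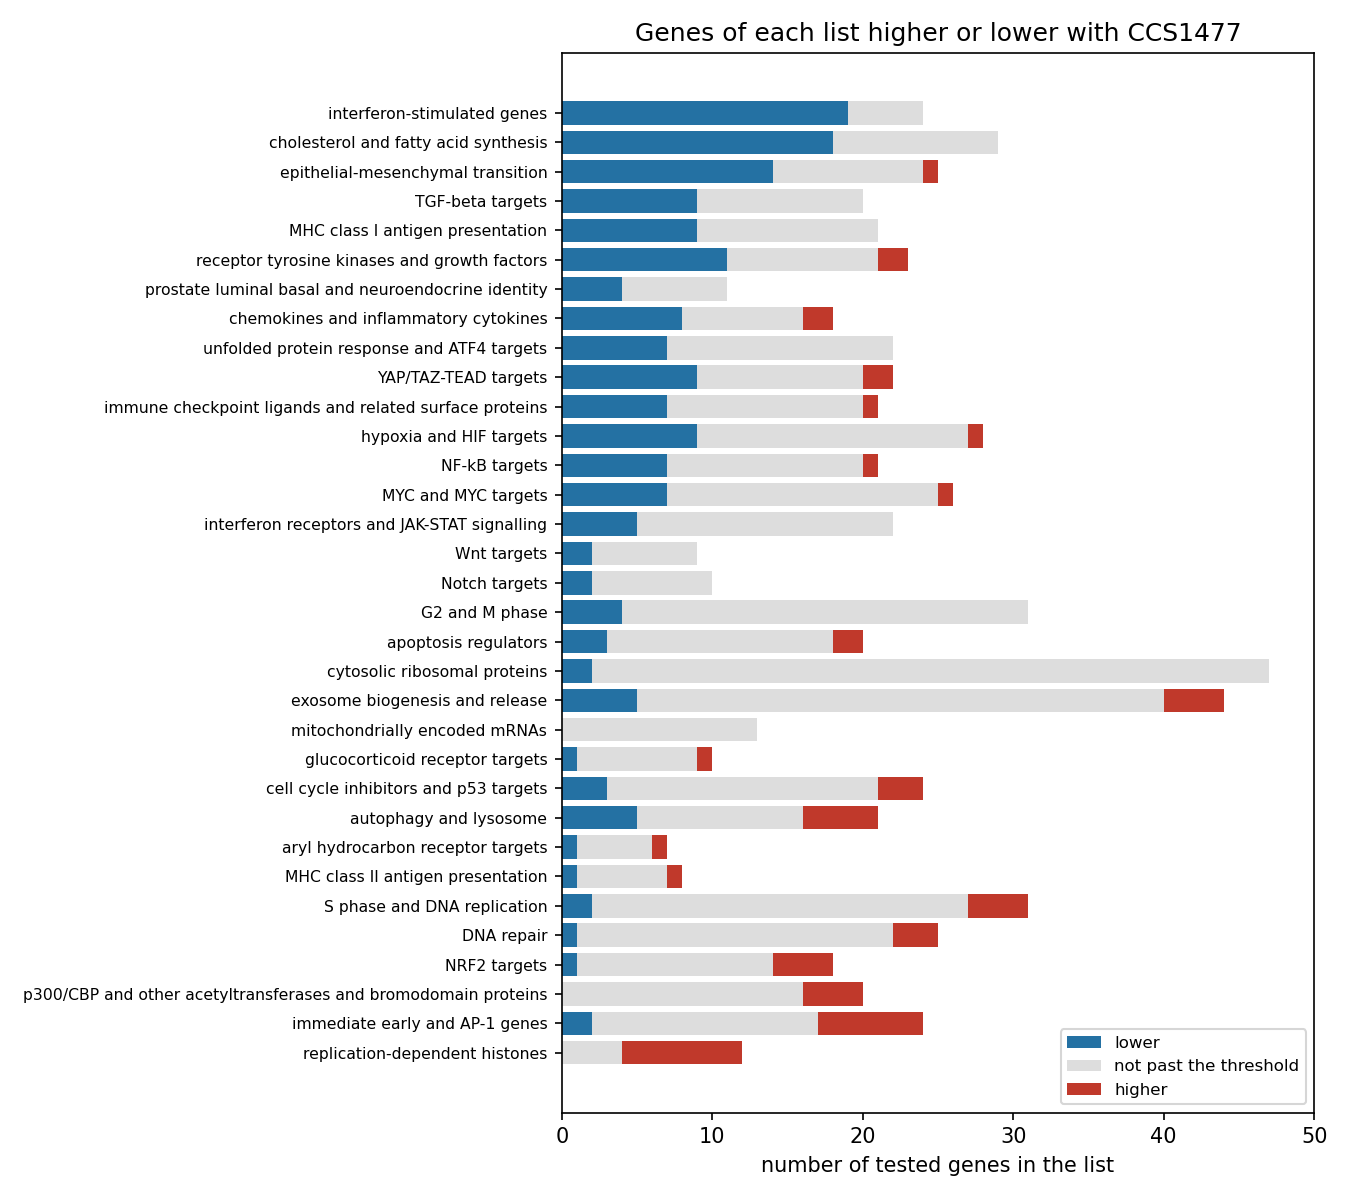
Number of tested genes per list (x axis) that were lower (blue), higher (red) or not past the threshold (grey) with CCS1477 in edgeR's quasi-likelihood test. Interferon-stimulated genes had 19 of 24 lower, and replication-dependent histones 8 of 12 higher.

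Over all tested genes, 7.23% were higher and 10.7% lower. The exosome list, 44 tested genes, had 4 higher and 5 lower (the same counts when adjusted over the list alone). Its median was 0.01 while camera's direction was down (adjusted p = 0.577). It had 2 higher without DMSO 1, 1 higher and 3 lower without CCS1477 2, and 1 higher without CCS1477 3. SDC1 and RAB31 fell by 1.16 and 1.34 on the log2 scale and PDCD6IP, the gene of the ESCRT partner ALIX, rose at 0.49. Cell cycle inhibitors and p53 targets had 3 higher, among them CDKN1A at 0.61, and 3 lower of 24 (the same when adjusted over the list alone), and apoptosis regulators 2 higher, MCL1 at 0.45 and BIRC2 at 0.39, and 3 lower of 20, among them BMF at -1.73 (2 and 4 when adjusted over the list alone). BMF stood at -0.31 and -0.51 on the log2(TPM + 1) and log2(TPM + 0.1) scales and did not pass there, where 0 apoptosis genes were lower. Autophagy and lysosome genes had 5 higher and 5 lower of 21, including the kinase ULK1 at 0.82 and the protease CTSL at -0.81 (the same counts when adjusted over the list alone). Without DMSO 1, CCS1477 2 or CCS1477 3, 2, 3 and 3 of them were higher, and 3 were lower without CCS1477 2. DNA repair genes had 3 higher and 1 lower of 25, the lower one being CHEK2 at -0.71 (the same when adjusted over the list alone). In the Notch list, 2 of 10 genes were lower, HES1 at -1.63 and NOTCH3 at -0.95, and in the Wnt list 2 of 9, NKD1 at -1.45 and DKK1 at -0.89 (2 in each when adjusted over the list alone). NKD1 stood at -0.01 and -0.35 on the log2(TPM + 1) and log2(TPM + 0.1) scales, and its call ended there and without DMSO 1, DMSO 2, CCS1477 1 or CCS1477 2. Prostate identity genes were lower in 4 of 11 cases, among them the keratin genes KRT7 at -0.53 and KRT15 at -1.45 (4 lower and 1 higher when adjusted over the list alone, and 2 lower without CCS1477 2). Glucocorticoid receptor targets had 1 higher, MT2A at 1.11, and 1 lower, the receptor NR3C1 at -0.51, of 10 (2 and 1 when adjusted over the list alone). Aryl hydrocarbon receptor targets had 1 higher and 1 lower of 7 (3 and 1 when adjusted over the list alone), with 3 higher when scaled by library size alone, 2 in DESeq2, with GC and length trends removed or without DMSO 3, and 0 without DMSO 1 or any 1 CCS1477 library. Of the 13 mitochondrially encoded mRNAs, 0 passed edgeR's test (0 when adjusted over the list alone), 3 had an unadjusted p under 0.05, DESeq2 called 1 lower and edgeR without a filter 5. None of these lists passed camera with all 6 libraries. The mitochondrial list passed without DMSO 1 (adjusted p = 0.0444) and without CCS1477 1 (adjusted p = 0.0148), the Wnt list without CCS1477 2 (adjusted p = 0.0484) and the DNA repair list without DMSO 2 (adjusted p = 0.0461).

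Markers of other cells were mostly below the filter. The fibroblast, endothelial and other prostate line lists had 1 tested gene each and 0 past the threshold, the list of HeLa, liver and blood markers had 0 tested, and the leukocyte list had 2, of which CD68, also a lysosomal protein of other cells, fell by 0.56 on the log2 scale. Across the 34 lists tested, camera called 14 lower and 4 higher at the preset correlation and 0 with an estimated correlation. Fry called 22, with 5 that camera did not call, among them the interferon receptor, exosome, prostate identity and Wnt lists, and without the ribosomal list (adjusted p = 0.336 by fry). Other splits of the 6 libraries gave up to 11 called lists at the preset correlation, against 18 for the real grouping. Limma on log2(TPM + 1) called fewer lower genes in most lists, with 5 in the epithelial-mesenchymal transition list, 3 in each of the receptor tyrosine kinase, hypoxia and checkpoint lists, 4 of the TGF-β genes, 2 YAP/TAZ-TEAD targets, 2 unfolded protein response genes, 1 interferon receptor or JAK-STAT gene and 1 MYC target, while NF-κB targets had 7. It also called fewer higher genes, with 5 histones, 2 immediate early genes (with 1 lower) and 2 NRF2 targets. Higher genes numbered 2 in the acetyltransferase and bromodomain list, 2 in the S phase list (with 0 lower) and 0 in DNA repair. The exosome list had 2 higher and 2 lower and the autophagy list 3 and 2. Further named genes whose calls ended on both TPM scales were STAT3, ERAP2, ERAP1, TAP2, NLRC5, SCD, INSIG1, MSMO1, SLC19A1, TGFB1, CCN1, ESRP2, NOTCH3, DKK1, NR3C1, CHEK2, BIRC2, ALDOA, TRIM28, RPL30, RPS23 and CD68. Lower MYC targets, unfolded protein response genes and G2 and M phase genes numbered 4, 4 and 2 with scaling by library size alone, and lower MYC targets 4 without a filter. Calls of several named genes ended without 1 library: TRIM28 and ULBP2 without CCS1477 3, KRT15 without CCS1477 2, TGFB1, ALDOA and CCN1 without CCS1477 2 or CCS1477 3, BIRC2 without DMSO 1, CCS1477 1 or CCS1477 2, and STAT3 without any 1 library but DMSO 3. That of SMARCA2 ended without any 1 library, that of RPL30 without DMSO 1 or any 1 CCS1477 library, and that of RPS23 without DMSO 3 or any 1 CCS1477 library, and without DMSO 3 the 2 ribosomal genes stood at -0.26 and -0.22.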

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

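Removal of GC and length trends, protein-coding genes only, the summed histone counts and their covariate were chosen after seeing the data. Against 1079 genes higher and 1597 lower, limma on log2(TPM + 1) gave 293 and 427 (94 and 229 by over 2-fold), and on log2(TPM + 0.1) 280 and 410 (125 and 258 by over 2-fold). The cause was not tested. An adjusted p under 0.01 gave 380 and 852, with 87 higher by over 2-fold, and glmTreat against a fold of 1.2 gave 369 and 846, both by asking for more. The stricter filter, which tests fewer genes, gave 80 and 249 by over 2-fold. Leaving out each library gave 487 to 1311 higher and 925 to 1772 lower genes, and 101 to 216 and 373 to 487 by over 2-fold. DESeq2 gave 1012 and 1439, voom 1090 and 1576, and removal of GC and length trends 1571 and 1941, keeping 98.4% of the calls. SMARCA2 reversed to -0.127 on the log2(TPM + 1) scale and -0.130 on the log2(TPM + 0.1) scale, and the cause was not tested. The replicate block gave 799 and 1306 (146 and 427 by over 2-fold) and kept 76.9% of the calls, with 0 higher aryl hydrocarbon receptor targets and no call for SMARCA2. Of all genes under the naming rule, 13 lost their call with the block and 1 gained one. Among list counts of at least 4 genes, 4 fell by over 1.5-fold with it. Deviations of same-numbered samples correlated at -0.09, -0.20 and -0.01, against -0.19 to 0.27 for differently numbered samples. No sample correlated best with its own number. With 3 samples per group these values showed no pairing by number but cannot exclude one. The median SE was 0.146 on the log2 scale. In the simulated data edgeR recovered 39.2% or 45.8% of the genes changed by 1.5-fold. Those simulations changed 200 genes, against 2676 genes called in the data, so their recovery does not carry over to this comparison.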

Other observations

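Tests chosen only after the result was seen were the family scan, the GC and length test of interferon-stimulated genes, the tests of carry-over and S phase for histones, and those of the lung-lineage genes. The splits, the matched random lists and the SERPINI1 test were written before their results were seen. Rules that an exclusion must also hold without each library in turn, and that the carry-over test must keep calls only where the fit without the covariate has them, were added after the values were known.

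The genes named in this paragraph, except MT2A, were chosen after their values were seen. Grouping tested genes by symbol prefix gave 442 families of 5 or more, of which camera called 3 higher and 4 lower, and 0 with an estimated correlation. Besides histones, keratin genes, which encode intermediate filaments and here include pseudogenes and an antisense gene, had 6 of 12 lower and 0 higher (camera adjusted p = 0.00116, and adjusted p = 0.894 with an estimated correlation). KRT80 fell from 146.8 ± 8.46 to 64.2 ± 1.47 CPM, while the abundant KRT8 was at 809.9 ± 60.0 and 790.2 ± 49.6 CPM and did not pass (n = 3). Organic anion transporter genes had 4 of 5 lower (camera adjusted p = 0.0092, and adjusted p = 0.894 with an estimated correlation), led by SLCO4A1, which fell from 400.7 ± 47.9 to 122.2 ± 2.31 CPM and whose antisense neighbour is among the 4. TNF receptor genes had 6 of 13 lower and 1 higher (camera adjusted p = 0.0383, and adjusted p = 0.894 with an estimated correlation), with TNFRSF1B at -1.59 and the higher gene, TNFRSF12A, at 0.66. The other 3 were the exocyst genes, with 3 of 10 higher, the KCNK potassium channels, with 2 of 5 lower, and the ZNF zinc finger genes, with 27 higher and 9 lower of 462 (camera adjusted p = 0.046 for each, and adjusted p = 0.894 with an estimated correlation). Both shares of the ZNF genes lay below those of all tested genes, 7.23% higher and 10.7% lower, and their median log2 fold change was 0.103. The metal-binding MT2A rose from 875.4 ± 36.3 to 1891 ± 254.2 CPM and MT1E at 0.55, while MT1X stood at 0.00.

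The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the only 1 of the 10 as large for each of 3 counts. It gave 2676 genes against 0 in the highest other split, 625 genes changed by over 2-fold against 0, and 18 gene lists against 11. At an unadjusted p under 0.05 the real split gave 4739 genes, and DESeq2 called 1012 higher and 1439 lower. The other splits keep part of the treatment difference, so their 5 to 11 called lists are not a pure count of false calls.

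Interferon-stimulated genes fell with a median log2 fold change of -1.03. With GC and length trends removed the median was -1.04, with 18 of 24 genes lower, and it stayed between -1.06 and -0.96 without each library, which argues against these trends as the cause. The lowest median of 10000 random lists matched on mean expression was -0.39, which argues against a general fall at that expression level. A response to CCS1477 may account for the fall as a hypothesis, which further doses, times or a second inhibitor would test, and none of these was in the design.

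Histone genes rose while the S phase list had a median of 0.028 against 0.685 for the histones. The gap of 0.657 was beyond 0.440, the combined SD of fold changes among the genes of both lists, which is not an error of the medians. As a list the S phase genes did not rise as the histones did, with 4 higher, such as CCNE2 at 0.88, and 2 lower, such as MCM5 at -0.34, of 31. How far they would rise with more cells in S phase was not tested, so this does not decide on the share of cells in S phase. RNAs without a poly-A tail summed to 22.8, 27.2 and 210 CPM in DMSO 1, 2 and 3 and 57, 46.8 and 26.9 in CCS1477 1, 2 and 3, against histone sums of 684.1, 698.6 and 643 and of 1146, 1297 and 1334 CPM, and without DMSO 3 they had a log2 fold change of 0.80 ± 0.23 (SE) against 0.86 for the histones. Most of these counts came from RN7SL1 and RN7SL2, named after their values were seen, with 155 and 97 in DMSO 1 and 793 and 906 in DMSO 3. Without DMSO 3 the sum of RNAs without a poly-A tail passed as higher (adjusted p = 0.022, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With its level as a covariate the chromosome 1 histones stood at 1.28 ± 0.08 and between 1.24 and 1.39 without each library. The chromosome 6 histones stood at 0.31 ± 0.07 and between 0.28 and 0.35, against 0.33 ± 0.09 without the covariate. The chromosome 6 sum did not pass without DMSO 1 or CCS1477 2, with or without the covariate, nor without CCS1477 3 in the fit that had no covariate. These values argue against carry-over that followed this level as the whole cause. A covariate made up mainly of RN7SL1 and RN7SL2 cannot exclude carry-over of histone RNA that did not follow them. Rises of BRD2, HEXIM1 and HIST2H2BE are also known under BET bromodomain inhibitors, and a shared response could be a candidate explanation. SERPINI1, named in advance as another such gene, had a log2 fold change of 0.43 ± 0.15 (adjusted p = 0.0698, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and MYC did not pass, so this cannot be told apart here.

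Genes of the lung lineage were expressed in cells labelled DU145. NKX2-1, a lung and thyroid transcription factor, stood at 105.6 ± 21.5 TPM in DMSO. Of 20 lung-lineage genes, listed after SFTPB, NAPSA, SFTA3, NKX2-1 and LMO3 had been noticed, 8 were tested. With CCS1477, 6 were lower, from -0.57 for NKX2-1 to -4.30 for SFTPB, but these include all those noticed first. Of the 3 others tested, SLC34A2 was lower, from 2.81 ± 1.11 to 0.618 ± 0.255 CPM (SD, n = 3). LAMP3 at -0.56 and AGER at -0.05 did not pass (adjusted p = 0.0857 and 0.925, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Against RNA of normal lung, the highest mean in DMSO of 5 abundant lung transcripts was 0.15 TPM, although SFTPB itself, left out of the 5 as part of the pattern, stood at 15.2 TPM. A lower share of 1 other cell type stays open. The fold changes of the 8 tested genes differed by more than their errors (Cochran Q = 276, and 15.3 for the 3 not noticed first). Unequal falls would also arise if the remaining cells express some of these genes, and no gene was higher. Another line or a mixture of lines under the DU145 label, with NKX2-1 at 105.63 TPM, may apply and cannot be told apart from expression in DU145 itself, since no genotype was used here.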
